A study of Arabidopsis thaliana with 24 samples.

How the data were processed

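Seedlings of Arabidopsis thaliana were grown, per the labels' protocols, at 22 °C on medium with 1% sucrose after 2 days of stratification, and 100 mg of seedlings per sample was collected at 4 days of age under dim green light. Libraries of 4 genotypes in 2 lights, 3 samples each, gave 24 libraries in 8 groups, assigned from the labels. RNA was extracted with a TaKaRa MiniBEST kit and the libraries were made and sequenced by BGI, per the labels' protocols. Per the submitters' processing notes the tools were HISAT2 and DESeq2 and the genome TAIR10, with no versions. The counting tool, its treatment of strand and of reads that map to several places, and the annotation release are not given in the sources used here. The deposited values, 1 per gene and library, were taken to be estimated counts, since their low values gathered at 4, 8, 12 and 16. They were whole numbers, so rounding them changed nothing. The share of multiples of 4 among values up to 40 was 25.9% to 30.2% per library, against 25% if values were spread evenly. That 1 fragment is worth 4 units is inferred from these values. All columns were used.

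The table listed 32833 genes, of which 4343 were 0 in every library. Of these identifiers 32548 (99.1%) matched the RefSeq gene table of TAIR10.1, which supplied symbols for 10804 genes and the coordinates given. Library totals were 71356146 units in wild type red replicate 1 and 81774008 to 88400230 in the others. CPM values are relative to the library's total over the genes tested, scaled by its TMM factor. Floors and counting intervals at 95% use 4 units as 1 fragment and 3 fragments (12 units) over a group as the floor, and they cover counting error only. Chloroplast-encoded genes took 0.015% to 0.084% of the units.

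Genes with low counts were removed with filterByExpr of edgeR 4.0.16 under R 4.3.3, which left 23445 and removed 9388. Libraries were scaled with TMM (factors 0.972 to 1.045), and all 24 were fitted together with 1 mean per group, using estimateDisp, glmQLFit with robust estimation and glmQLFTest. The common dispersion was 0.0155, a biological coefficient of variation of 0.124. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and the standard error of a log2 change was its size divided by the square root of the test's F. Comparisons were each mutant against wild type and the double mutant against each single mutant within a light, red against blue wild type, the difference of each genotype's effect between lights (blue minus red), and the departure of the double mutant from the sum of the single mutants' effects in each light. The steps were tested on simulated counts: for npr1-1 against wild type in blue, over 23272 genes, 72 of 100 genes changed by a log2 of 0.5 and 94 of 100 changed by 1 were recovered, with 8 false calls among 174.

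Before the data were examined, 17 gene lists of 386 distinct genes were fixed: genes induced by PIF factors, auxin response, brassinosteroid and gibberellin, cell wall expansion, salicylic acid defence, jasmonate, light-harvesting proteins, photosystem and Rubisco, chlorophyll synthesis, flavonoid and anthocyanin, light signalling, HY5 and blue light markers, clock, root markers, seed reserve markers, cell cycle, and heat and handling stress. Each was tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, and again with an estimated correlation and with fry; adjusted p-values of lists are Benjamini-Hochberg values over the lists of a comparison. Named genes were NPR1 and PIF4 in every comparison. In the 3 comparisons of a mutant with wild type in blue, the double mutant against npr1-1 in blue and red against blue wild type, the 5 genes with the highest and the 5 with the lowest log2 change were added among called genes with at least 5 CPM in the higher group and no overlap of replicates, plus the 2 called members with the smallest adjusted p of each list with at least 3 called. In other comparisons these numbers were 3, 3 and 1, and in interactions 3 positive and 3 negative genes with at least 5 CPM in the highest group.

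Overlaps of calls were set against independent lists and against 10 simulations of unchanged groups with the same shared libraries. Alternatives tried were DESeq2 size factors in edgeR, the Wald test of DESeq2 1.42.0, no filter on low counts, the replicate number as a block, only the groups compared in the fit, a minimum log2 change of 1 and leaving out each replicate. Comparisons that share no library, with 1 library of the shared group in one and the other 2 in the other, dividing the values by 4, list tests with DESeq2 size factors or with a library left out, and list tests with an estimated correlation under these and the block, were added after seeing the data. Genes that overlap another gene, and members of families with near-identical copies, are uncertain because strand and shared reads were handled in a way the sources used here do not give.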

Results

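RNA was sequenced from 24 samples of whole Arabidopsis thaliana seedlings, collected at 4 days of age from continuous blue light at 5 µmol per square metre and second or continuous red light at 15 µmol. In each light there were 3 samples labelled wild type (Col-0), 3 labelled npr1-1, 3 labelled pif4-2 and 3 labelled with both mutations, pif4-2 npr1-1. NPR1 is a transcription co-regulator best known from salicylic acid signalling, and PIF4 is a transcription factor that promotes elongation growth and is controlled by light. The series asks how the 2 genes act together in seedling development under blue light. The deposited values summed to between 71356146 and 88400230 units per library, the lowest being wild type red replicate 1 and the next lowest 81774008. Low values gathered at 4, 8, 12 and 16, so 1 sequenced fragment may be worth 4 units. After removal of genes with low counts, 23445 genes were tested. Levels below are CPM, the units of a gene relative to the library total, as mean ± SD over the 3 samples of a group, and log2 changes carry their standard error. A gene is said to have risen or fallen only where its adjusted p from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was under 0.05. The labels do not say whether the samples of a group came from separate cultures, so p-values measure only the spread between these samples.

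NPR1 (AT1G64280, chromosome 1, 23852748 to 23855658 on the minus strand of TAIR10.1, 1 annotated transcript with 4 exons) had group means between 23.9 and 32.4 CPM. In blue it stood at 31.6 ± 1.6 CPM in wild type, 30.1 ± 1.1 in npr1-1, 29.4 ± 0.8 in pif4-2 and 32.4 ± 1.1 in the double mutant, and in red at 26.0 ± 0.8, 23.9 ± 0.6, 26.4 ± 1.4 and 25.7 ± 1.0 in the same order. No genotype comparison within a light called NPR1 with edgeR, although DESeq2 gave a log2 change of -0.14 in npr1-1 under red (adjusted p 0.047). PIF4 (AT2G43010, chromosome 2, 17886101 to 17889087 on the plus strand, 5 annotated transcripts of 6 to 7 exons) was lower in both single mutants. In blue it fell from 100.9 ± 12.7 CPM in wild type to 60.5 ± 1.5 in npr1-1 (log2 -0.74 ± 0.11, edgeR adjusted p 7e-05) and to 77.1 ± 8.1 in pif4-2 (log2 -0.39 ± 0.11, edgeR adjusted p 0.024). The double mutant held 111.2 ± 14.5 CPM in blue, a log2 change of 0.14 ± 0.11 from wild type that did not pass (edgeR adjusted p 0.46). In red PIF4 fell from 86.1 ± 4.4 CPM to 61.0 ± 6.3 in npr1-1, 62.1 ± 6.2 in pif4-2 and 57.5 ± 5.3 in the double mutant. The departure of the double mutant from the sum of the single mutants' effects was 1.27 ± 0.15 for PIF4 in blue (edgeR adjusted p 1.1e-05) and 0.38 ± 0.15 in red (edgeR adjusted p 0.24). The call of PIF4 in pif4-2 under blue was lost when only the 2 groups were fitted (adjusted p 0.077) and without wild type replicate 2 (0.11) or 3 (0.11) or pif4-2 replicate 1 (0.071) or 2 (0.11), and under red without pif4-2 replicate 1 (0.064). The npr1-1 allele is a point mutation and pif4-2 an insertion, and a count over the whole gene does not check either label. PIF4 reads were not lost from the libraries labelled pif4-2 or pif4-2 npr1-1, so genotype names throughout stand for the labels.

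**Figure D1:**
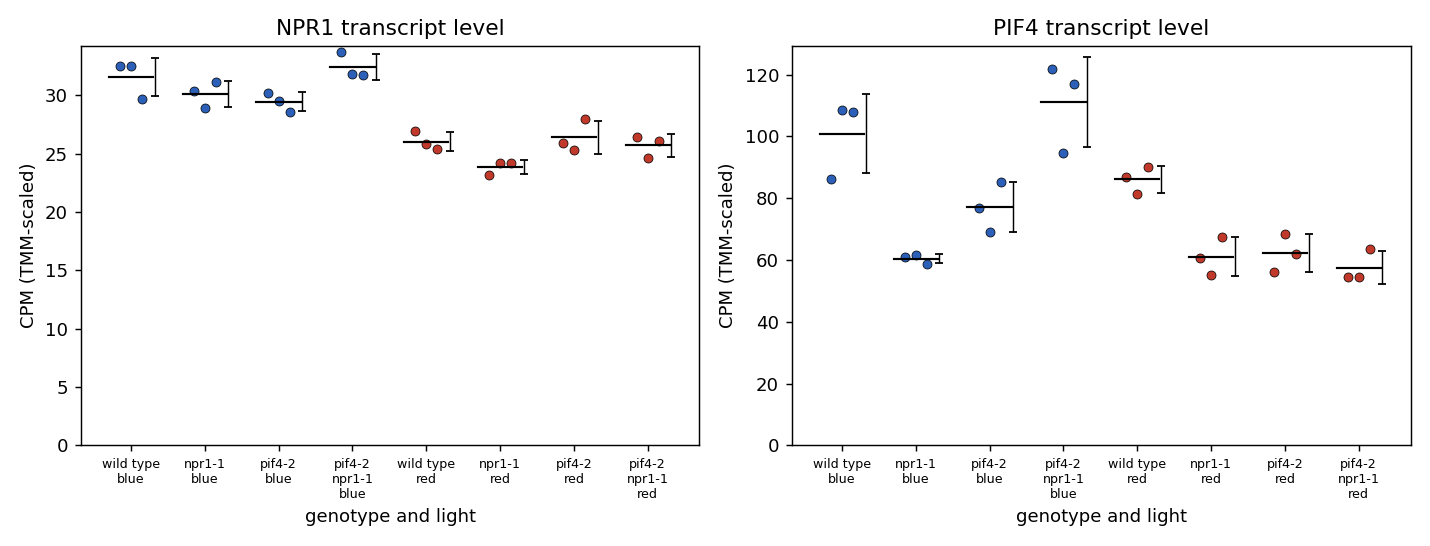
NPR1 and PIF4 levels in every library, in CPM, by genotype and light; points are libraries, horizontal lines group means and bars 1 SD. NPR1 means lie between 23.9 and 32.4 CPM; PIF4 in blue is highest in the double mutant (111.2 CPM) and lowest in npr1-1 (60.5 CPM).

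Loss of NPR1 function under blue light was compared with wild type to ask which transcripts depend on it there. In blue-grown npr1-1 seedlings, 11 of 17 seed reserve, 13 of 20 flavonoid, 11 of 18 cell cycle and 7 of 24 jasmonate genes rose, while 15 of 21 light-harvesting and 12 of 20 clock genes fell and 2 and 4 rose. None of these list tests passed with an estimated correlation (adjusted p 0.14 to 0.31). GEA6, a late embryogenesis protein, rose from 2.94 ± 1.02 to 27.9 ± 4.85 CPM (log2 3.24 ± 0.30), and VSP2, a jasmonate-induced storage protein, rose from 8.65 ± 1.32 to 22.6 ± 4.87 CPM (log2 1.39 ± 0.15). LHCB2.1, a light-harvesting protein of photosystem II, fell from 2030 ± 124 to 1350 ± 104 CPM (log2 -0.58 ± 0.08). The strongest rises were of HSP17.6A, a small heat shock protein (0.287 to 14 CPM), QQS, a regulator of starch content (0.511 to 20.7 CPM), ATECP31, a seed maturation protein (0.332 to 12.5 CPM), AT1G68250 (4.97 to 149 CPM) and AT1G03106 (1.25 to 23.7 CPM). AT3G29633 (10.6 to 0.0732 CPM), AT1G64795 (19.2 to 0.52 CPM), AT3G05945 (15.0 to 0.443 CPM), AT3G55920 (11.8 to 0.88 CPM) and FRO4, a ferric reductase (12.9 to 1.42 CPM), fell most. AT3G29633 and AT1G64795 were near 0 in blue pif4-2 as well, so their falls do not go with the npr1-1 label alone. In all, edgeR called 6164 genes, 2896 higher and 3268 lower, of which 610 differed by a log2 of at least 1, 436 higher and 174 lower.

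Of the 17 seed reserve genes tested in blue npr1-1, 11 rose and 0 fell (12 and 0 adjusted over the list alone). The median log2 change was 2.08, with a camera adjusted p of 2.2e-10, or adjusted p = 0.14 with an estimated correlation. ABI5, a transcription factor of seed maturation and germination, rose by 0.94 ± 0.11 alongside GEA6. Of 20 flavonoid genes 13 rose and 0 fell (19 and 0 adjusted over the list alone), among them FLS1, flavonol synthase (0.92 ± 0.17), and PAL1, the entry enzyme of the phenylpropanoid pathway (0.35 ± 0.06). The median was 1.91, with a camera adjusted p of 3.3e-08, or adjusted p = 0.31 with an estimated correlation. Of 18 cell cycle genes 11 rose and 0 fell (12 and 0 adjusted over the list alone), including CYCA1;1, an A-type cyclin (0.68 ± 0.10), and CDC20.1, an activator of the anaphase-promoting complex (0.64 ± 0.08). Their median was 0.44, with a camera adjusted p of 3.3e-08, or adjusted p = 0.16 with an estimated correlation. Of 24 jasmonate genes 7 rose and 0 fell (8 and 0 adjusted over the list alone). The median was 0.61, with a camera adjusted p of 5.8e-05, or adjusted p = 0.31 with an estimated correlation. Cell wall expansion genes rose in 10 of 24 cases and fell in 2 (11 and 2 adjusted over the list alone), with XTH33 at 0.84 ± 0.11 and EXPA4 at 0.39 ± 0.06. Their median was 0.20 and the camera adjusted p 0.0028, or adjusted p = 0.31 with an estimated correlation. Without wild type replicate 1 that call was lost (adjusted p 0.059). Of 20 heat and handling genes 4 rose and 1 fell (4 and 1 adjusted over the list alone). The median was 0.37, with a camera adjusted p of 0.022, or adjusted p = 0.31 with an estimated correlation.

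Most photosynthesis genes tested fell in blue npr1-1. Of 21 light-harvesting genes 15 fell and 2 rose (17 and 3 adjusted over the list alone). The median was -0.29 and the camera adjusted p 7.6e-05, or adjusted p = 0.31 with an estimated correlation. Of 25 photosystem and Rubisco genes 17 fell and 2 rose (18 and 2 adjusted over the list alone). The median was -0.25 and its camera adjusted p 3.2e-06, or adjusted p = 0.31 with an estimated correlation. PSAL and PSBR, subunits of photosystem I and II, changed by -0.48 ± 0.08 and -0.45 ± 0.08. Of 20 clock genes 12 fell and 4 rose (13 and 4 adjusted over the list alone), with AT5G64170 (LNK1) at -0.78 ± 0.07 and PRR3 at 0.73 ± 0.08. Their median was -0.28, with a camera adjusted p of 0.0011, or adjusted p = 0.31 with an estimated correlation. Of 18 HY5 and blue light markers 9 fell and 3 rose (9 and 3 adjusted over the list alone), including SIGE, a plastid sigma factor (-0.92 ± 0.10), and STO, the B-box protein BBX24 (-0.64 ± 0.06). The median was -0.22, with a camera adjusted p of 0.0083, or adjusted p = 0.14 with an estimated correlation. Of 26 light signalling genes 5 fell and 1 rose (4 and 1 adjusted over the list alone), among them PIL6, which is PIF5 (-0.74 ± 0.07), and PIF7 (-0.58 ± 0.10). Their median was -0.09, with a camera adjusted p of 0.023, or adjusted p = 0.31 with an estimated correlation. Of 23 genes induced by PIF factors 9 fell and 1 rose (9 and 1 adjusted over the list alone). The median was -0.26, with a camera adjusted p of 0.014, or adjusted p = 0.42 with an estimated correlation. HFR1 (-0.84 ± 0.11) and HB-2, a shade-induced homeodomain factor (-0.76 ± 0.12), fell in that list, whose camera call was lost without wild type replicate 3 (adjusted p 0.18). The camera test did not pass for 5 lists. They were auxin response (3 of 35 rose and 8 fell, 3 and 8 adjusted over the list alone, adjusted p 0.095), brassinosteroid and gibberellin (4 of 27 rose and 5 fell, 4 and 5 adjusted over the list alone, adjusted p 0.14) and salicylic acid defence (4 of 29 rose and 0 fell, 3 and 0 adjusted over the list alone, adjusted p 0.11), and also chlorophyll synthesis (5 of 17 rose and 5 fell, 6 and 5 adjusted over the list alone, adjusted p 0.60) and root markers (6 of 23 rose and 4 fell, 6 and 5 adjusted over the list alone, adjusted p 0.81). Without wild type replicate 1 the first 2 passed, with medians of -0.28 (adjusted p 0.0018) and -0.13 (adjusted p 0.021). In the salicylic acid list ALD1, an enzyme of pipecolic acid synthesis (1.65 ± 0.33), and AT4G10500, a salicylic acid hydroxylase (1.98 ± 0.20), rose. In the chlorophyll list PORA and PORB, protochlorophyllide oxidoreductases, rose by 3.3 ± 0.30 and 1.08 ± 0.09. Light-harvesting and Rubisco genes have near-identical copies whose reads the counting could have divided, so values of single members are uncertain.

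**Figure D2:**
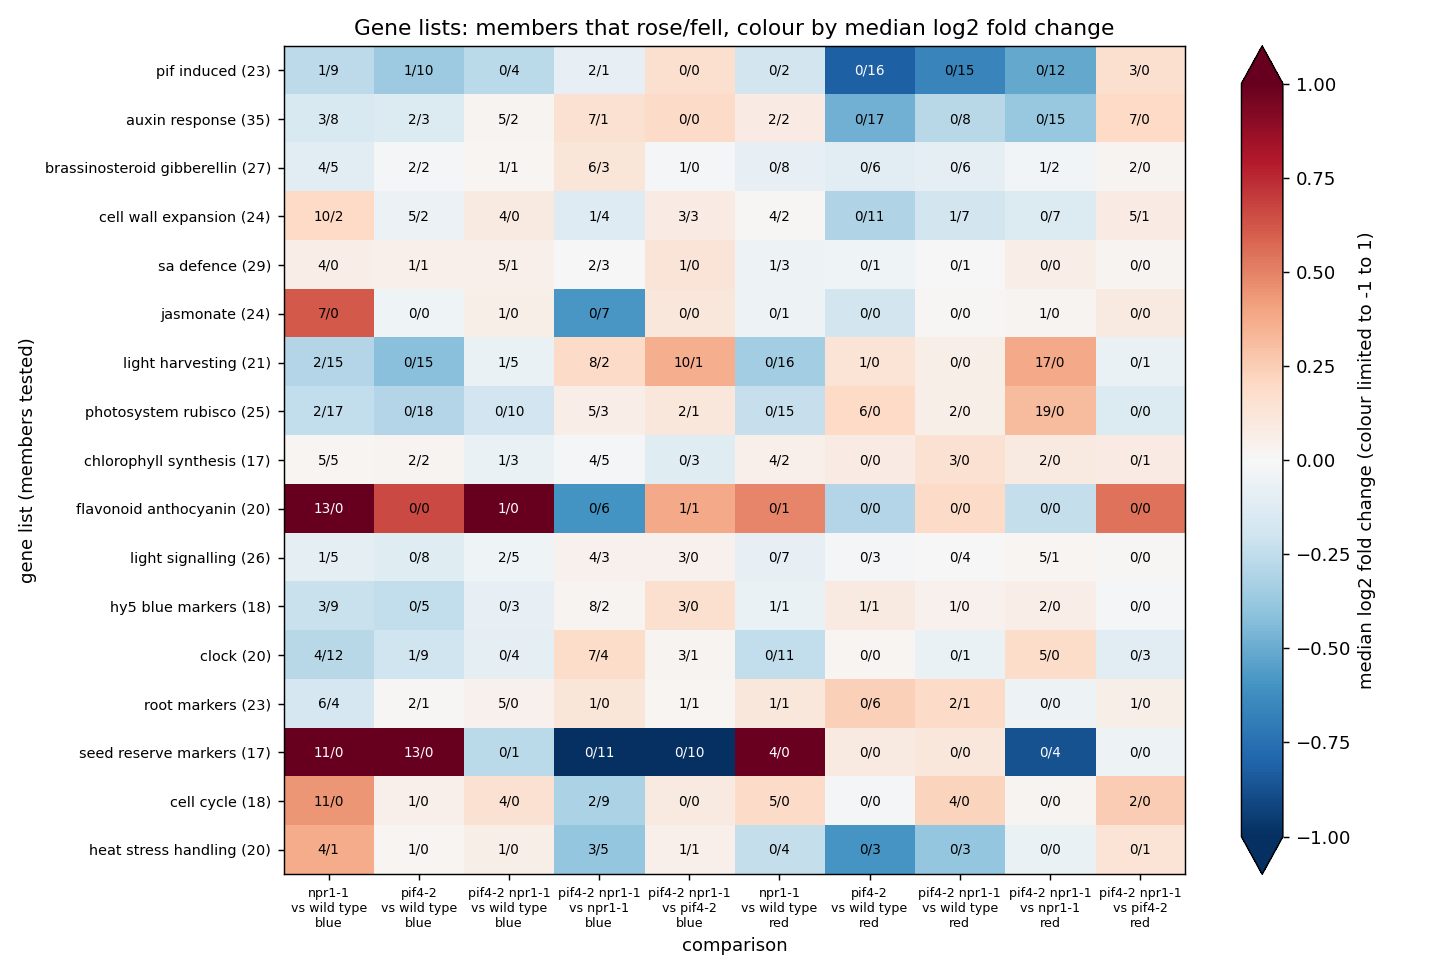
Members of 17 gene lists that rose and fell (numbers in each cell, rose/fell) in the 10 genotype comparisons, with lists in rows, comparisons in columns and colour giving the median log2 fold change. Seed reserve genes read 11/0 and 13/0 in blue npr1-1 and pif4-2 and 0/1 in the blue double mutant; PIF-induced genes read 0/16 in red pif4-2.

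In blue-grown seedlings labelled pif4-2 most seed reserve genes rose and most photosynthesis genes fell against wild type, and 10 of 23 genes that PIF factors induce fell. With an estimated correlation the adjusted p was 0.025 for seed reserve genes, 0.093 for both photosynthesis lists and 0.19 for PIF-induced genes. Seed reserve genes rose in 13 of 17 cases and fell in 0 (16 and 0 adjusted over the list alone), with GEA6 at 12.8 ± 5.11 CPM against 2.94 ± 1.02 in wild type and ABI3, a seed maturation regulator, at 9.76 ± 1.67 against 4.77 ± 0.329. Their median was 2.61 and the camera adjusted p 1.7e-17, or adjusted p = 0.025 with an estimated correlation. Light-harvesting genes fell in 15 of 21 cases and rose in 0 (17 and 0 adjusted over the list alone). The median was -0.42, with a camera adjusted p of 3.7e-14, or adjusted p = 0.093 with an estimated correlation. Photosystem and Rubisco genes fell in 18 of 25 cases and rose in 0 (23 and 0 adjusted over the list alone). The median was -0.29 and the camera adjusted p 1.7e-17, or adjusted p = 0.093 with an estimated correlation. Of the PIF-induced genes 10 of 23 fell and 1 rose (11 and 2 adjusted over the list alone), led by ST2A, a sulfotransferase (96.4 ± 15.0 to 35.7 ± 3.07 CPM, log2 -1.43 ± 0.15), and IAA29, an auxin response repressor (33.5 ± 5.99 to 17 ± 2.31 CPM, log2 -0.97 ± 0.12). The median was -0.36 and its camera adjusted p 6.5e-06, or adjusted p = 0.19 with an estimated correlation (0.047 without wild type replicate 1). Clock genes fell in 9 of 20 cases and rose in 1 (13 and 2 adjusted over the list alone), including PRR9 (-1.02 ± 0.14). Camera gave this list an adjusted p of 1.6e-05, or adjusted p = 0.16 with an estimated correlation. Light signalling genes fell in 8 of 26 cases and rose in 0 (9 and 0 adjusted over the list alone), among them PHOT2, a blue light receptor (-0.30 ± 0.05). The list's camera adjusted p was 2.6e-05, or adjusted p = 0.035 with an estimated correlation (0.074 without pif4-2 replicate 2). HY5 and blue light markers fell in 5 of 18 cases and rose in 0 (7 and 1 adjusted over the list alone). Camera gave this list an adjusted p of 0.00036, or adjusted p = 0.025 with an estimated correlation. Beyond the lists, EPR1, a cell wall protein of germinating seeds, rose from 1.94 ± 0.992 to 44.5 ± 13.5 CPM. FBA5, a fructose-bisphosphate aldolase (88.8 to 26.9 CPM), COR413IM1, a cold-regulated chloroplast membrane protein (61.2 to 20.9 CPM), and AT1G61300 (11.3 to 3.99 CPM) fell. AT3G29633, read at 8 units over the 3 libraries, fell to a level 354 times lower (95% counting interval 98 to 2920). SESA1, a seed storage albumin (2.44 to 93.2 CPM), was called with an adjusted p of 0.020, which was lost with only the 2 groups in the fit (0.085) and without wild type replicate 2 (0.076) or 3 (0.082) or pif4-2 replicate 3 (0.062). edgeR called 2646 genes, 1316 higher and 1330 lower, and 187 higher and 55 lower by a log2 of at least 1. The count was 1296 without wild type replicate 2, 1609 without wild type replicate 3 and 1607 without pif4-2 replicate 1.

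Among the calls of the 2 blue single mutants, 1548 genes went in the same direction, 737 higher in both and 811 lower in both, and 57 in opposite directions. Independent lists of these sizes would share 163 higher, 185 lower and 348 opposite. Unchanged groups simulated against the same wild type libraries shared 0 in each of 10 simulations, but they hold no true differences to call, so that count does not measure what the shared libraries add to 1548. Across genes the log2 changes had a covariance of 0.250, against 0.0582 from the shared wild type libraries in the simulations, and a correlation of 0.56 against 0.50. In 6 divisions chosen after seeing the data, 1 wild type library served one comparison and the other 2 the other, so that none was shared. They gave 247 to 645 genes in the same direction, with 70 to 138 for independent lists, a covariance of 0.0914 to 0.208 and a correlation of 0.12 to 0.27. Fewer libraries stood behind each comparison there, and part of the excess with all libraries may come from sharing them. The overlap was 756 without wild type replicate 2 and 929 without wild type replicate 3. The opposite calls numbered 32, 18 and 22 without wild type replicates 1, 2 and 3, 35 without npr1-1 replicate 3, and 28 and 30 without pif4-2 replicates 1 and 3.

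**Figure D3:**
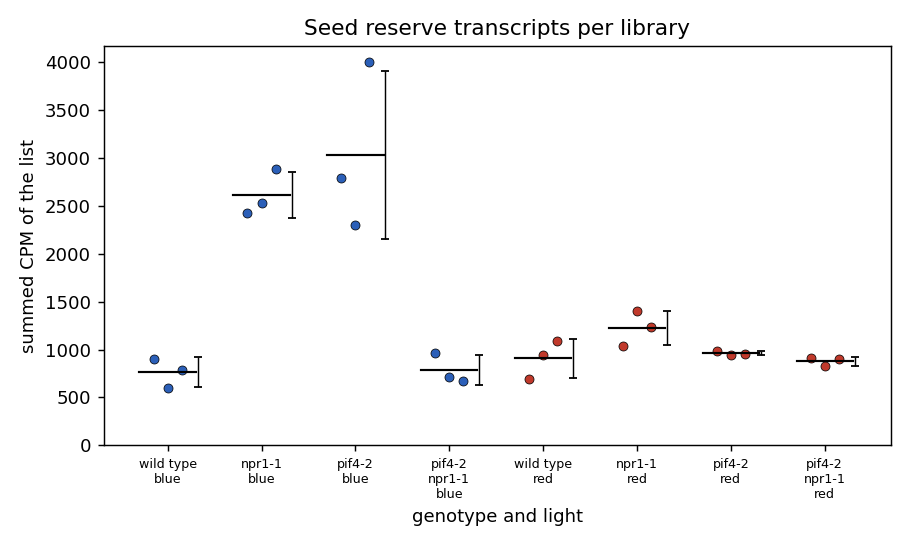
Summed level of the 17 seed reserve genes in every library, in CPM, by genotype and light; points are libraries, lines group means and bars 1 SD. In blue all 6 npr1-1 and pif4-2 libraries lie above the highest wild type or double mutant library.

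In blue light the double mutant was compared with wild type and with each single mutant to ask whether the npr1-1 changes need PIF4. Few of its seed reserve and jasmonate genes passed the test against wild type, while several changes seen in npr1-1 stayed. Of the seed reserve genes 0 of 17 rose and 1 fell against wild type (0 and 1 adjusted over the list alone). Their median was -0.27, with a camera adjusted p of 0.34. The list passed without wild type replicate 2 (median -0.64, adjusted p 0.0029) and without double mutant replicate 1 (-0.92, 0.015). CRA1, a 12S storage globulin taken as an example after its values were seen, stood at 28.6 CPM in the double mutant, 59.3 in wild type, 711 in npr1-1 and 713 in pif4-2. Light-harvesting genes fell in 5 of 21 cases and rose in 1 (5 and 1 adjusted over the list alone). The median was -0.07, with a camera adjusted p of 0.017, or adjusted p = 0.78 with an estimated correlation. That camera call was lost without wild type replicate 2 (0.09) or 3 (0.054), and the median turned to 0.02 without double mutant replicate 2 (adjusted p 0.49). Photosystem and Rubisco genes still fell in 10 of 25 cases and rose in 0 (18 and 0 adjusted over the list alone), with RCA, Rubisco activase, at -0.53 ± 0.09. Their median was -0.19, with a camera adjusted p of 7.5e-09, or adjusted p = 0.64 with an estimated correlation. Of the PIF-induced genes 4 of 23 fell and 0 rose (4 and 0 adjusted over the list alone), including ST2A (-1.13 ± 0.15) and IAA29 (-0.81 ± 0.12). The list's camera adjusted p was 0.0066, or adjusted p = 0.71 with an estimated correlation. This camera call was lost without wild type replicate 3 (0.12) or double mutant replicate 2 (0.067). In the flavonoid list 1 of 20 rose and 0 fell (1 and 0 adjusted over the list alone). The median was 1.06 (camera adjusted p 0.64). It passed in opposite directions when single libraries were left out, at 1.47 without double mutant replicate 1 (adjusted p 0.0012) and -0.41 without double mutant replicate 2 (adjusted p 0.0019). In the jasmonate list 1 of 24 rose and 0 fell (0 and 0 adjusted over the list alone). Its median of 0.06 (camera adjusted p 0.92) became -0.20 (camera adjusted p 0.014) without double mutant replicate 2. Salicylic acid defence genes rose in 5 of 29 and fell in 1 (7 and 2 adjusted over the list alone, camera adjusted p 0.45). Cell cycle genes rose in 4 of 18 cases and fell in 0 (5 and 1 adjusted over the list alone). Their median was 0.15, with a camera adjusted p of 0.017, or adjusted p = 0.74 with an estimated correlation. This camera call was lost without wild type replicate 3 (0.054) or double mutant replicate 1 (0.15). Some npr1-1 changes stayed. QQS stood at 13.3 ± 0.947 CPM (log2 4.70 ± 0.24 above wild type) and AT4G04223 at 27.7 ± 0.602 against 3.93 ± 0.531. AT3G05945 stood at 0.19 ± 0.114 against 15.0 ± 1.11 and AT3G55920 at 0.559 ± 0.14 against 11.8 ± 0.27, while AT1G64795 stood at 0.00766 CPM against 19.2. edgeR called 3001 genes against wild type, 1461 higher and 1540 lower, a count that was 908 with only the 2 groups in the fit and 1788 without wild type replicate 2.

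Against blue npr1-1, 11 of 17 seed reserve, 7 of 24 jasmonate, 6 of 20 flavonoid and 9 of 18 cell cycle genes fell in the double mutant, and 2 cell cycle genes and PIF4 (0.88 ± 0.11, edgeR adjusted p 1.1e-05) rose. None of these list tests passed with an estimated correlation (adjusted p 0.15 to 0.62), but that of seed reserve genes did without double mutant replicate 1 (0.035) and that of flavonoid genes without double mutant replicate 2 (0.044). Seed reserve genes fell in 11 of 17 cases and rose in 0 (11 and 0 adjusted over the list alone). The median was -1.62, with a camera adjusted p of 1.4e-12, or adjusted p = 0.15 with an estimated correlation. Jasmonate genes fell in 7 of 24 and rose in 0 (7 and 0 adjusted over the list alone), with VSP2 at -1.27 ± 0.15 and CLH1 at -0.92 ± 0.17. Their median was -0.58 and the camera adjusted p 9.4e-05, or adjusted p = 0.62 with an estimated correlation. Flavonoid genes fell in 6 of 20 and rose in 0 (6 and 0 adjusted over the list alone). The median was -0.60, with a camera adjusted p of 3.8e-07, or adjusted p = 0.61 with an estimated correlation. Cell cycle genes fell in 9 of 18 and rose in 2 (12 and 2 adjusted over the list alone). The median was -0.32 and the camera adjusted p 9.4e-05, or adjusted p = 0.61 with an estimated correlation. Heat and handling genes fell in 5 of 20 and rose in 3 (5 and 3 adjusted over the list alone). The median was -0.39, with a camera adjusted p of 0.047, or adjusted p = 0.62 with an estimated correlation. That call was lost with DESeq2 size factors (0.059), without npr1-1 replicate 2 (0.088) or 3 (0.066) and without double mutant replicate 1 (0.18) or 3 (0.061). Of 21 light-harvesting genes 8 rose and 2 fell (camera adjusted p 0.044, or 0.62 with an estimated correlation). Of 35 auxin response genes 7 rose and 1 fell (0.03, or 0.62). Both calls were lost without double mutant replicate 1 (0.28 and 0.18). Photosystem and Rubisco genes did not revert as a list, as 5 of 25 rose and 3 fell (median 0.07, camera adjusted p 0.73). AIR1, an auxin-induced root gene (28.4 ± 1.56 to 123 ± 23.1 CPM), and CIPK20, a protein kinase (10.2 ± 3.14 to 34.1 ± 7.39 CPM), rose. AT1G68250 (149 to 1.17 CPM), AT1G03106 (23.7 to 0.498 CPM) and HSP17.6A (14 to 0.31 CPM) fell. ATECP31, at 9 units over the double mutant libraries, was 367 times lower (95% counting interval 109 to 2550). edgeR called 5395 genes, 2942 higher and 2453 lower, or 3287 with only the 2 groups in the fit. By a log2 of at least 1, 126 were higher and 363 lower. Of the 6164 genes called in blue npr1-1, 2960 (48.0%) were called in the opposite direction between the double mutant and npr1-1, and 51 in the same direction again. Independent lists would give 713, and simulated double mutants with npr1-1 means, which hold no true difference to call, gave 0 at most. With the npr1-1 libraries divided so that none was shared, 971 to 1358 genes were opposite over 6 divisions, with 181 to 269 for independent lists. Of the 2960, 264 were also called between the double mutant and wild type, counted in either direction. Of all the npr1-1 calls, 1380 were called in the double mutant in the same direction. Against blue pif4-2, the double mutant had lower seed reserve transcripts, of which 10 of 17 fell and 0 rose (16 and 0 adjusted over the list alone). The median was -2.97 and its camera adjusted p 5e-26, or adjusted p = 0.0094 with an estimated correlation. Light-harvesting genes rose in 10 of 21 cases and fell in 1 (13 and 1 adjusted over the list alone). Their median was 0.36, with a camera adjusted p of 4.1e-08, or adjusted p = 0.49 with an estimated correlation. ABI3 fell by 1.79 ± 0.16 and CAB2, a light-harvesting protein, rose by 0.55 ± 0.08. edgeR called 1150 genes there, 508 higher and 642 lower (37 and 191 by a log2 of at least 1), a count that was 347 with only the 2 groups in the fit, 657 and 735 without pif4-2 replicates 2 and 3, and 725, 1826 and 587 without double mutant replicates 1, 2 and 3.

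In red light most light-harvesting and photosystem genes and 11 of 20 clock genes fell in npr1-1 seedlings. None of these list tests passed with an estimated correlation (adjusted p 0.46). Light-harvesting genes fell in 16 of 21 cases and rose in 0 (18 and 0 adjusted over the list alone), with CAB1 falling from 22900 ± 1730 to 16600 ± 1350 CPM. The median was -0.35, with a camera adjusted p of 4.5e-08, or adjusted p = 0.46 with an estimated correlation. Photosystem and Rubisco genes fell in 15 of 25 and rose in 0 (18 and 1 adjusted over the list alone). Their median was -0.23, with a camera adjusted p of 1.7e-07, or adjusted p = 0.46 with an estimated correlation. Clock genes fell in 11 of 20 and rose in 0 (14 and 0 adjusted over the list alone), among them FKF1, a blue light receptor of the clock (-0.68 ± 0.09). The median was -0.25, with a camera adjusted p of 1.8e-06, or adjusted p = 0.46 with an estimated correlation. Seed reserve genes rose in 4 of 17 cases and fell in 0 (5 and 0 adjusted over the list alone). Their median was 0.99 and the camera adjusted p 0.00071, or adjusted p = 0.46 with an estimated correlation. Cell cycle genes rose in 5 of 18 cases and fell in 0 (5 and 0 adjusted over the list alone). The median was 0.19 and the camera adjusted p 0.0014, or adjusted p = 0.46 with an estimated correlation. That call was lost without npr1-1 replicate 2 (0.052). Heat and handling genes fell in 4 of 20 and rose in 0 (4 and 0 adjusted over the list alone). Their median was -0.24, with a camera adjusted p of 0.072. PIF-induced genes fell in 2 of 23 and rose in 0 (2 and 0 adjusted over the list alone). Camera gave this list an adjusted p of 0.15. Light signalling genes fell in 7 of 26 and rose in 0, with a camera adjusted p of 0.022, or adjusted p = 0.46 with an estimated correlation. Brassinosteroid and gibberellin genes fell in 8 of 27 and rose in 0 (camera adjusted p 0.061). That list passed without wild type replicate 1 (0.025) or npr1-1 replicate 3 (0.018). Salicylic acid defence genes rose in 1 of 29 and fell in 3 (camera adjusted p 0.19). QQS (0.288 ± 0.138 to 25.6 ± 5.12 CPM) and AT4G04223 (3.47 ± 0.694 to 21.3 ± 0.627 CPM) rose as in blue, and AT3G29633, AT3G05945 and AT3G55920 fell. HDG7, a homeodomain protein gene, read 21 ± 14 against 2.69 ± 0.686 CPM (edgeR adjusted p 0.035), but it trades reads with the overlapping gene AT5G52180 and its call was lost with only the 2 groups in the fit (0.073), with the values divided by 4 (0.051), without any one of wild type replicates 1 (0.11), 2 (0.10) and 3 (0.074), and without npr1-1 replicate 2 (0.13) or 3 (0.054). edgeR called 4997 genes, 2576 higher and 2421 lower, and 145 higher and 145 lower by a log2 of at least 1.

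In red-grown pif4-2 seedlings many growth genes that PIF factors and auxin control fell. PIF-induced genes fell in 16 of 23 cases and rose in 0 (19 and 0 adjusted over the list alone). The median was -0.82, with a camera adjusted p of 2.7e-28, or adjusted p = 0.0075 with an estimated correlation. PIL1, a shade-induced helix-loop-helix factor, fell from 4.13 ± 0.469 to 0.638 ± 0.249 CPM (log2 -2.70 ± 0.19), and ST2A fell from 49.8 ± 4.76 to 10.8 ± 1.63 CPM (log2 -2.21 ± 0.16). Auxin response genes fell in 17 of 35 and rose in 0 (24 and 0 adjusted over the list alone), including IAA6 (-1.93 ± 0.18), which both lists hold. The median was -0.48 and the camera adjusted p 9e-24, or adjusted p = 0.044 with an estimated correlation. The latter was 0.053 and 0.088 without wild type replicates 2 and 3, and 0.058 and 0.069 without pif4-2 replicates 1 and 2. Cell wall expansion genes fell in 11 of 24 and rose in 0 (14 and 1 adjusted over the list alone), with XTH19, a xyloglucan endotransglucosylase, at -0.81 ± 0.08. The median was -0.30 and its camera adjusted p 1.3e-12, or adjusted p = 0.023 with an estimated correlation (0.053 without wild type replicate 3). Photosystem and Rubisco genes rose in 6 of 25 and fell in 0 (16 and 0 adjusted over the list alone). Their median was 0.20, with a camera adjusted p of 1e-09, or adjusted p = 0.27 with an estimated correlation. Some members of other lists fell too. Heat and handling genes, kept as markers of stress in the samples, fell in 3 of 20 and rose in 0 (9 and 0 adjusted over the list alone). The median was -0.59, with a camera adjusted p of 1.8e-06, or adjusted p = 0.06 with an estimated correlation. Brassinosteroid and gibberellin genes fell in 6 of 27 and rose in 0 (9 and 0 adjusted over the list alone). Their median was -0.11 and the camera adjusted p 8.6e-06, or adjusted p = 0.17 with an estimated correlation. Root markers fell in 6 of 23 and rose in 0 (6 and 2 adjusted over the list alone). The median was 0.24, opposite in sign to the calls, with a camera adjusted p of 0.87. AT3G01345 rose from 0.432 ± 0.147 to 47.6 ± 5.15 CPM, and AT3G29633, at 4 units over the 3 libraries, was 566 times lower than in wild type (95% counting interval 102 to 22400). edgeR called 1260 genes, 505 higher and 755 lower. The count was 1948 with only the 2 groups in the fit, and 712, 747 and 837 without pif4-2 replicate 1, 2 and 3. With npr1-1 calls in red, 339 genes were shared in direction, 123 higher and 216 lower, and 129 were opposite. Independent lists would give 55, 78 and 135, and 10 simulations of unchanged groups, which hold no true difference to call, gave 0. The covariance was 0.149 against 0.0570 simulated and the correlation 0.39 against 0.51. With the wild type libraries divided so that none was shared, 48 to 109 genes went in the same direction (18 to 56 for independent lists) and 26 to 101 were opposite (18 to 58). The covariance was then 0.00474 to 0.0483 and the correlation 0.01 to 0.08. With wild type replicate 1 alone in the npr1-1 comparison, 100 genes agreed in direction and 101 were opposite. With wild type replicate 3 alone in the pif4-2 comparison, 55 agreed and 66 were opposite. Part or most of the excess with all libraries may come from sharing them, though fewer libraries stood behind each divided comparison. The overlap was 210 without wild type replicate 1, 188 and 207 without pif4-2 replicates 1 and 2, and 530 with DESeq2. The opposite calls numbered 64 and 66 without wild type replicates 2 and 3, 79 without pif4-2 replicate 1, 79 without pif4-2 replicate 2, and 195 with DESeq2.

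In the red double mutant many PIF-induced genes fell against wild type and npr1-1, and most photosynthesis genes rose against npr1-1. None of these list tests passed with an estimated correlation (adjusted p 0.076 to 0.084). Against wild type, PIF-induced genes fell in 15 of 23 and rose in 0 (18 and 0 adjusted over the list alone), with PIL1 at -2.39 ± 0.19. The median was -0.66, with a camera adjusted p of 4.6e-16, or adjusted p = 0.076 with an estimated correlation. Auxin genes fell in 8 of 35 and rose in 0 (13 and 1 adjusted over the list alone). Their median was -0.28, with a camera adjusted p of 1.8e-07, or adjusted p = 0.34 with an estimated correlation. Cell wall expansion genes fell in 7 of 24 and rose in 1 (9 and 1 adjusted over the list alone). The median was -0.18, with a camera adjusted p of 0.00062, or adjusted p = 0.34 with an estimated correlation. Heat and handling genes fell in 3 of 20 and rose in 0 (3 and 0 adjusted over the list alone). Their median was -0.39, with a camera adjusted p of 0.00081, or adjusted p = 0.34 with an estimated correlation. Cell cycle genes rose in 4 of 18 and fell in 0 (9 and 0 adjusted over the list alone). The median was 0.22 and the camera adjusted p 1.7e-05, or adjusted p = 0.34 with an estimated correlation. Against red npr1-1, PIF-induced genes fell in 12 of 23 and rose in 0 (14 and 0 adjusted over the list alone). The median was -0.51, with a camera adjusted p of 5.7e-14, or adjusted p = 0.084 with an estimated correlation. Light-harvesting genes rose in 17 of 21 and fell in 0 (19 and 0 adjusted over the list alone). Their median was 0.38 and the camera adjusted p 1.5e-17, or adjusted p = 0.084 with an estimated correlation. Photosystem and Rubisco genes rose in 19 of 25 and fell in 0 (22 and 0 adjusted over the list alone). The median was 0.32, with a camera adjusted p of 6.4e-22, or adjusted p = 0.084 with an estimated correlation. Seed reserve genes fell in 4 of 17 and rose in 0 (6 and 0 adjusted over the list alone). The median was -0.87, with a camera adjusted p of 5e-06, or adjusted p = 0.20 with an estimated correlation. AT2G14247 rose by a log2 of 3.45 ± 0.42 to 12.6 ± 3.32 CPM and AT3G01570 fell from 9.73 ± 3.59 to 0.92 ± 0.301 CPM. Against red pif4-2, IAA6 rose by 1.23 ± 0.18, NAC044, a NAC transcription factor, rose from 1.09 ± 0.188 to 6.14 ± 0.562 CPM, and AT3G01345 fell from 47.6 ± 5.15 to 0.687 ± 0.0747 CPM. edgeR called 2297 genes against wild type (1205 higher, 1092 lower), 1450 against npr1-1 (800 higher, 650 lower) and 933 against pif4-2 (495 higher, 438 lower). By a log2 of at least 1 the balance turned, with 68, 62 and 37 higher and 114, 102 and 71 lower in that order. Of the 4997 npr1-1 calls in red, 962 (19.3%) were opposite between the double mutant and npr1-1, with 154 for independent lists and 0 in simulations that hold no true difference to call. With no npr1-1 library shared they numbered 67 to 486, with 10 to 117 for independent lists. The count against wild type was 1500 and 1463 without wild type replicates 2 and 3, and 1225 and 1052 without double mutant replicates 1 and 2. Against npr1-1 it was 872 and 709 without double mutant replicates 1 and 3. The opposite calls numbered 605 without npr1-1 replicate 2 and 624 and 475 without double mutant replicates 1 and 3. Against pif4-2 it was 579, 539 and 427 without pif4-2 replicates 1, 2 and 3, 406 and 367 without double mutant replicates 1 and 2, 2756 with only the groups compared and 1428 with DESeq2.

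Red-grown wild type was compared with blue-grown wild type to describe the light response itself. HY5 and blue light markers were lower in red, with 16 of 18 lower and 0 higher (16 and 0 adjusted over the list alone). The median was -1.19 and the camera adjusted p 6.4e-07, or adjusted p = 0.0014 with an estimated correlation. SIGE, of this list, fell from 127 ± 7.69 CPM in blue to 16.7 ± 0.962 in red. HFR1, a factor that promotes light development and a member of the PIF-induced list, fell from 193 ± 20.9 to 7.91 ± 1.11. Light signalling genes were lower in 18 of 26 cases and higher in 3 (18 and 3 adjusted over the list alone), including PHYB, the red light receptor (-1.21 ± 0.05), and SPA1 (-1.17 ± 0.05). The median was -0.46 and its camera adjusted p 8.7e-05, or adjusted p = 0.068 with an estimated correlation. The latter was 0.019, 0.039 and 0.037 without red wild type replicates 1, 2 and 3. Clock genes were lower in 14 of 20 cases and higher in 4 (14 and 4 adjusted over the list alone). Their median was -0.98, with a camera adjusted p of 0.00059, or adjusted p = 0.41 with an estimated correlation. Photosystem and Rubisco genes were higher in red in 19 of 25 cases and lower in 1 (19 and 1 adjusted over the list alone). The median was 0.55, with a camera adjusted p of 2.6e-06, or adjusted p = 0.47 with an estimated correlation. Light-harvesting genes were higher in 16 of 21 cases and lower in 1 (16 and 2 adjusted over the list alone). Their median was 0.46, with a camera adjusted p of 0.00045, or adjusted p = 0.55 with an estimated correlation. Cell cycle genes were higher in 14 of 18 cases and lower in 0 (14 and 0 adjusted over the list alone). The median was 0.82, with a camera adjusted p of 3.6e-06, or adjusted p = 0.32 with an estimated correlation. PORA and PORB were at 76.7 ± 4.71 and 1480 ± 60.8 CPM in red against 2.89 ± 1.19 and 158 ± 13.4 in blue, and CRK30, a receptor-like kinase, and UMAMIT36, a transporter, rose from 0.238 to 16.1 and from 0.223 to 14.8 CPM. Transcripts encoded in the chloroplast made up 0.018% ± 0.003 of the units in red wild type and 0.053% ± 0.0 in blue. Mitochondrial ones made up 0.008% ± 0.0 and 0.019% ± 0.001. Both shares were lower in every red group than in every blue group. Group means were 0.018% to 0.023% against 0.053% to 0.074% for the chloroplast, and 0.006% to 0.008% against 0.017% to 0.019% for mitochondria. A response to light was not separated here from a difference in library preparation. AT1G12310 read 60.5 ± 2.62 CPM in blue and 0 in red, at least 1190-fold lower by a floor of 3 fragments over the group. The overlapping AT1G12320 read 3.98 and 83.2 CPM, and the sum of the pair was 64.4 ± 2.31 in blue and 83.2 ± 1.41 in red. PP2-A10 read 31.6 CPM in blue and 0.0596 in red and the overlapping AT1G10150 read 6.29 and 19, with a sum that fell from 37.9 to 19. AT5G04905 read 0.632 and 33.8 CPM and the overlapping AT5G28919 read 88.9 and 11.7, with a sum that fell from 89.6 to 45.5. edgeR called 13974 genes, 6794 higher in red and 7180 lower. Light was confounded with the light's intensity, and blue and red samples cannot be separated from any difference in when they were grown or prepared.

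**Figure D4:**
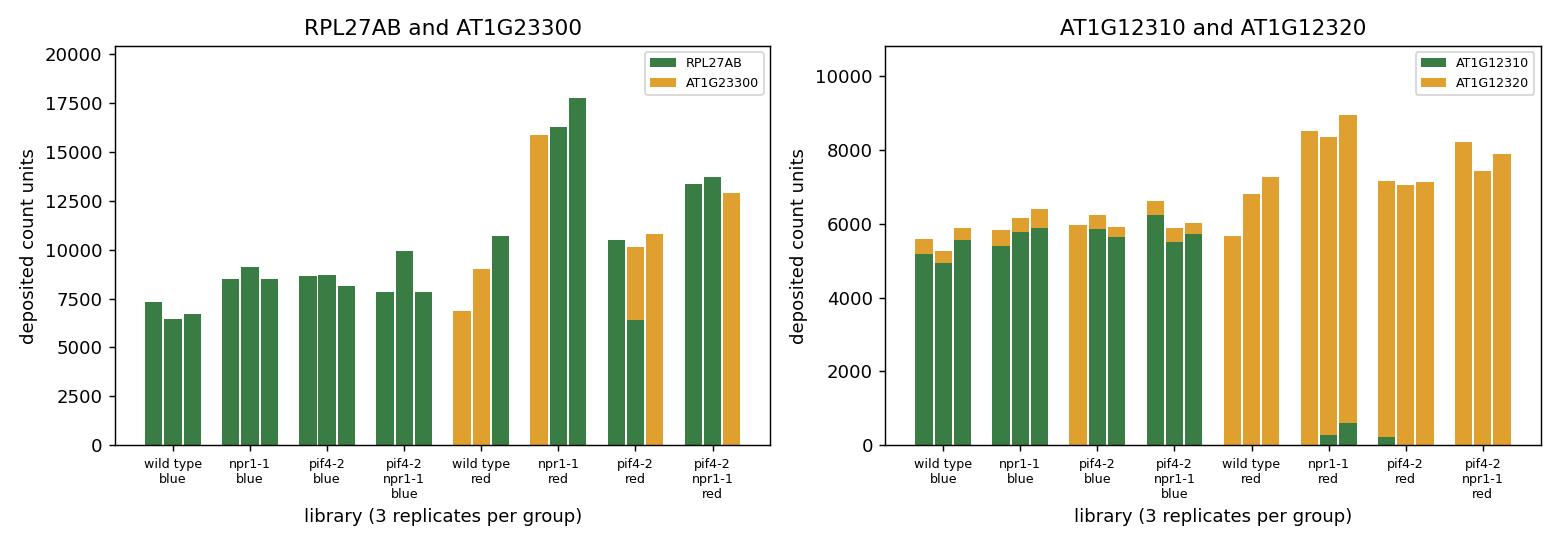
Deposited units of 2 pairs of overlapping genes in every library, stacked by gene, with 3 libraries per group along the horizontal axis. In red wild type the units of AT1G12310 are at 0 and those of AT1G12320 are higher than in blue, and RPL27AB and AT1G23300 replace each other between libraries of the same red group.

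Whether genotype effects differed between the lights was tested as an interaction. The pif4-2 effect differed most clearly in gene groups: photosystem and Rubisco genes had a more negative effect in blue in 21 of 25 cases and a more positive one in 0 (23 and 0 adjusted over the list alone). Their median was -0.52 and the camera adjusted p 1.5e-24, or adjusted p = 0.041 with an estimated correlation. Seed reserve genes had a more positive one in 6 of 17 and a more negative one in 0 (12 and 0 adjusted over the list alone). The median was 2.35, with a camera adjusted p of 8.6e-13, or adjusted p = 0.041 with an estimated correlation. PIF-induced genes had a more positive pif4-2 effect in blue in 8 of 23 cases and a more negative one in 0 (11 and 0 adjusted over the list alone). The median was 0.52 and the camera adjusted p 3.7e-08, or adjusted p = 0.12 with an estimated correlation. For npr1-1, jasmonate genes had a more positive effect in blue in 4 of 24 cases and a more negative one in 0 (4 and 0 adjusted over the list alone). The median was 0.71 and its camera adjusted p 3.6e-05, or adjusted p = 0.44 with an estimated correlation. edgeR called 2345 genes for npr1-1, 1486 for pif4-2 and 1064 for the double mutant, and 4443 genes in blue and 208 in red for the departure of the double mutant from the sum of the single mutants. The first was 1545 without blue npr1-1 replicate 3, the second 955 without blue wild type replicate 2, and the third 657 without red double mutant replicate 2, 660 with only the groups compared and 1699 with DESeq2. The red departure was between 62 and 470 with single libraries left out, 617 with only the groups compared and 753 with DESeq2. Of the 208, 81 (38.9%) were positive and 127 negative, a division that became 101 (51.3%) against 96 with DESeq2 size factors.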

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

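Of the tests in this part, those of a single seed source, of a few libraries, of overlapping genes, of mislabelled libraries, of shared npr1-1 libraries and of a difference of the blue libraries only were chosen after the results had been seen.

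The npr1-1 effect differed between lights, by edgeR's test of the difference, for 2345 genes, the pif4-2 effect for 1486 and the double mutant's effect for 1064. The double mutant departed from the sum of the single mutants for 4443 genes in blue and 208 in red. For genes, all differences below are log2 and were tested in the same way. For npr1-1, blue minus red, HSP17.6A stood at 5.52, ATECP31 at 4.66, COR15B at 4.01, FRO4 at -3.71, FRO5 at -3.65 and COPT2 at -2.90. The call of ATECP31 was lost with only the groups compared in the fit (adjusted p 0.06) and without red wild type replicate 2 (0.11). For pif4-2, ATECP31 stood at 5.67, EPR1 at 4.48, AT1G68250 at 4.44, AT3G01345 at -6.06, CIPK20 at -2.72 and AT2G15020 at -2.72. Here ATECP31 lost its call with only the groups compared (0.09) and without red wild type replicate 2 (0.078). AT1G68250 lost it with only the groups compared (0.13), without blue wild type replicates 2 (0.058) and 3 (0.073), blue pif4-2 replicates 1 (0.052) and 3 (0.084), red wild type replicates 2 (0.056) and 3 (0.097), and red pif4-2 replicates 1 (0.068), 2 (0.076) and 3 (0.05). For the double mutant, PIF4 stood at 0.72, EXPA17 at 2.93, UMAMIT36 at 2.90, AT2G43620 at 2.60, AT1G64795 at -5.91, FRO4 at -2.68 and AT2G15020 at -2.17. AT2G15020 lost its call with no filter on low counts (0.057), only the groups compared (0.086) and the values divided by 4 (0.071). It also lost it without each of blue wild type replicates 1 to 3 (0.068, 0.083 and 0.067), blue double mutant replicates 1 to 3 (0.062, 0.064 and 0.065), red wild type replicates 2 and 3 (0.054 and 0.091) and red double mutant replicates 2 and 3 (0.18 and 0.069). UMAMIT36 lost its call with only the groups compared (0.065) and without blue wild type replicates 1 (0.065) and 2 (0.057). AT2G43620 lost its call with only the groups compared (0.11), with the values divided by 4 (0.063), and without blue wild type replicates 2 (0.065) and 3 (0.052), red wild type replicate 1 (0.069) and red double mutant replicates 1 (0.063), 2 (0.055) and 3 (0.064). The blue departure was 1.27 for PIF4, 8.70 for AT3G29633, 2.74 for CIPK20, 2.61 for PGAZAT, -12.44 for ATECP31, -10.83 for AT1G68250 and -10.12 for AT5G04905, which trades reads with an overlapping gene and lost its call with only the groups compared (0.054). The red departure was 8.54 for AT3G29633, 3.24 for AT2G14247, 2.06 for AT5G05250, -7.04 for AT3G01345, -3.87 for QQS and -3.80 for AT1G65090. There AT3G29633 lost its call without wild type replicates 1 (0.069) and 2 (0.059), pif4-2 replicates 1 (0.085), 2 (0.073) and 3 (0.056), npr1-1 replicate 2 (0.074) and double mutant replicates 2 (0.25) and 3 (0.12), each in red. AT5G05250 lost it without red wild type replicates 1 (0.07) and 2 (0.057), pif4-2 replicates 1 (0.081) and 3 (0.069), npr1-1 replicate 1 (0.063) and double mutant replicates 2 (0.056) and 3 (0.061). Values of AT3G29633, AT1G64795 and ATECP31 rest on groups close to 0 and depend on the prior count. In the gene lists, the pif4-2 effect differed between lights by camera with an estimated correlation. The median was 0.39 for cell wall expansion, -0.52 for photosystem and Rubisco, -0.35 for HY5 and blue light markers and 2.35 for seed reserve genes. With the replicate block each lost that camera call (adjusted p 0.071, 0.071, 0.076 and 0.071 in this order).

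Other divisions of the same libraries were counted in fits of only the groups compared. With 3 samples against 3 there are 10 divisions, too few for a share under 0.05. In blue the real one called 5456 genes for npr1-1 against wild type (highest other 2), 2064 for pif4-2 (3), 908 for the double mutant (4), 3287 for the double mutant against npr1-1 (1) and 347 against pif4-2 (5). In red the values were 3627 (1), 1948 (4), 3240 (2), 1553 (2) and 2756 (2) in the same order, and red against blue wild type gave 13240 (0). For the differences between lights and the departures, 25 divisions were counted, the real one included, with genotype labels exchanged within each light. The real one called 1875 genes for npr1-1 (highest other 814), 1589 for pif4-2 (444) and 660 for the double mutant (216). For the blue departure of the double mutant it called 3305 (1). Chance cannot be excluded for the red departure, where 2 of 25 divisions, the real one included, gave 617 or more. The highest other gave 1245 there. Exchanged labels mix genotypes that differ, so these divisions bear on any genotype effect. They cannot decide whether an effect differs between lights or departs from the sum.

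Seed reserve transcripts were higher in blue npr1-1 and pif4-2 than in blue wild type and the double mutant. That a few libraries carried them is argued against for 11 of 17 members. These had all 6 npr1-1 and pif4-2 libraries above the highest wild type or double mutant library. For 1 gene and a division fixed in advance this has a chance of 0.108%, but the division was chosen after the values were seen. A few libraries cannot be told apart as the source for the other 6, CRU2, SESA1, SESA2, SESA3, SESA4 and PCK1, in which 2 to 5 of the 6 libraries lay above. A share of seeds or late seedlings that varied between samples is a candidate explanation, but it was not separated from regulation. Within groups the list's members deviated together, with a mean pairwise correlation across genes of 0.398 against a highest value of 0.103 in 1000 random lists. Those lists were matched on mean expression only, and genes regulated together would deviate together as well. RNA of 1 seed source in differing amounts cannot be told apart from gene regulation here: with 1 ratio of excess for all 17 members, their log2 levels in npr1-1 had an SD of 1.13 around the fit, and 390 and 239 of 1000 simulations with such a ratio, with gene-wise dispersions and with resampled library deviations, gave as much. GEA6 (log2 1.12) and ABI5 (0.47) were higher in npr1-1 than in pif4-2 by edgeR's test, while SESA1 stood at -3.17 (edgeR adjusted p 0.09), and regulation of these genes by NPR1 and PIF4 stays open and untested.

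In 38 genes a library of a group read near 0, at most 12 units, while another of that group read 1000 units or more. Library depth is argued against, because the libraries near 0 had a mean depth rank of 2.03 where 1 is the shallowest of 3. Reads of overlapping genes counted for one gene or the other may be the source: of the 33 such genes that overlap another, 90.9% traded values with it, against at most 6.06% with random partners. Some of the 33 are both genes of a pair, such as RPL27AB and AT1G23300, so they are not independent cases. The other 5 overlap no gene, and as 4 of them are the seed reserve genes CRU2, SESA1, SESA2 and SESA5 and 1 is LDOX, a flavonoid gene, this source leaves them open. The measure replaced an earlier one that was saturated, and a biological explanation was not tested.

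In blue, 2960 of the genes called in npr1-1 were called in the opposite direction between the double mutant and npr1-1. A swap of the double mutant libraries with wild type or pif4-2 ones is argued against by 15 genes that mark npr1-1 and the double mutant in red. On these the lowest of the 3 blue double mutant libraries lay at 0.99, from wild type at 0 to npr1-1 at 1. The highest blue pif4-2 library lay at 0.17. HDG7, which trades reads, is among these genes. They mark the lines and do not check the npr1-1 allele itself. The pif4-2 label of the double mutant libraries cannot be decided: the lowest lay at 0.67 on the like scale to pif4-2. That rests on only 4 genes, on which an npr1-1 library reached 0.52, and PIF4 itself stood at 111.2 CPM. The shared npr1-1 libraries as the whole source are argued against, since with none shared the reverted genes were at least 4.9 times as many as independent lists give. A difference of preparation or stage in the blue libraries cannot be told apart: 72.8% of the genes had the same sign of npr1-1 effect in red, between the 62.7% of all genes and the 80.4% of the other npr1-1 calls, and of those called in red 799 were in the same direction and 130 opposite, but as all genes pass the bound of 60% it decides nothing, and a requirement of PIF4 for the npr1-1 changes is a hypothesis that stays open.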

How the results depend on the processing

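Dividing the values by 4, list tests with DESeq2 size factors or a library left out, alternatives to list tests with an estimated correlation and comparisons that share no library were chosen after seeing the data. Of the 22 counts, DESeq2 size factors, no filter, the replicate block and the values divided by 4 left each within 1.5 times. A minimum log2 change of 1 left, in blue, 610 genes for npr1-1, 242 for pif4-2, 247 for the double mutant, 489 for the double mutant against npr1-1 and 228 against pif4-2, and in red 290, 153, 182, 164 and 108. It left 2947 for the light, 371, 263 and 201 for the differences between lights, 637 and 46 for the departures in blue and red, 164 and 22 for the overlaps, 4 and 8 for opposite calls and 249 and 71 for reverted calls; the cause is the fewer genes that pass. The DESeq2 Wald test gave 1428 for the double mutant against pif4-2 in red, 1699 for its difference between lights, 753 for the red departure, and 530 shared and 195 opposite calls in red. Fits of only the groups compared were not run for overlaps and reverted calls. In blue they gave 908, 3287 and 347 for the double mutant against wild type, npr1-1 and pif4-2. In red they gave 1948 for pif4-2 and 2756 for the double mutant against pif4-2. The double mutant's difference between lights and the red departure came to 660 and 617. The main fit shares 1 estimate of spread over all groups, but replicates differed unequally. Between pairs of replicates the chi-square per degree of freedom was 10.68 to 21.49 in the blue double mutant and 2.79 to 3.59 in red pif4-2. In the other groups it lay between 3.97 and 13.57. Whether this spread moved the counts was not tested. With each library left out in turn, counts ranged in blue from 4136 to 6344 (npr1-1), 1296 to 2875 (pif4-2), 1788 to 2868 (double mutant), 3842 to 6213 (against npr1-1) and 587 to 1826 (against pif4-2). In red they ranged from 3528 to 5251, 712 to 926, 1052 to 1842, 709 to 1161 and 367 to 808 in that order. The light gave 13061 to 13391, the differences between lights 1545 to 2403, 955 to 1567 and 657 to 1375, and the departures 3219 to 6015 and 62 to 470. Overlaps ranged from 756 to 1888 in blue and 188 to 475 in red, opposite calls from 18 to 69 and 64 to 125, and reverted calls from 2050 to 3659 and 475 to 946. With no library shared, shared calls were 247 to 645 in blue and 48 to 109 in red, opposite calls 10 to 67 and 26 to 101, and reverted calls 971 to 1358 and 67 to 486; fewer libraries stood behind each comparison. A single library or a lone pair of libraries in a group was assumed to vary like the other groups. Of the named genes called in the main fit or in the alternative, none turned in sign. Turns of genes called in neither were not counted. With a library left out 126 gene results lost their call and 3 gained one, and with only the groups compared 33 lost it. With the values divided by 4, 4 gene results lost their call, and with no filter 2. Of 238 list results, 97 lost their call with an estimated correlation and none gained one, and with fry 32 lost and 11 gained one. With DESeq2 size factors 3 lost and 1 gained a call. With a library left out 26 lost and 38 gained one, not counting 6 whose median turned in sign and whose call changed too. With libraries left out, the median of cell wall expansion in blue pif4-2 ranged from -0.12 to 0.08. It turned without wild type replicate 3, where the list passed (camera adjusted p 0.04). For the blue double mutant against wild type, jasmonate ranged from -0.20 to 0.17, light-harvesting from -0.20 to 0.02 and flavonoid from -0.41 to 1.47. Against pif4-2, jasmonate ranged from -0.29 to 0.28 and flavonoid from -1.11 to 0.72. These 5 double mutant medians turned without its replicate 2, so that library decides them. Without it jasmonate and flavonoid passed against pif4-2, at medians of -0.29 (camera adjusted p 0.012) and -1.11 (camera adjusted p 4.6e-08). The cause was not tested. Replicate numbers share only a number: same-numbered libraries of different groups had a median correlation of -0.03 in blue and 0.01 in red, and 2 and 4 of 12 libraries correlated best with their own number. With the replicate block the counts were, for example, 6221 for npr1-1 and 2775 for pif4-2 in blue, 12646 for the light and 300 for the red departure, and no count moved by over 1.5 times. With it 8 gene results lost their call, among them the differences between lights of AT1G68250 for pif4-2 (adjusted p 0.06) and of AT2G15020 (0.066) and UMAMIT36 (0.05) for the double mutant, and the departures of AT5G04905 in blue (0.059) and AT3G29633 in red (0.052), while 3 list results gained one. With an estimated correlation the block ended 7 list calls, in blue pif4-2 those of seed reserve (0.063), HY5 (0.063) and light signalling genes (0.086), and for the pif4-2 difference between lights those of seed reserve, photosystem and cell wall expansion (each 0.071) and HY5 genes (0.076), and 1 was gained, heat and handling in red pif4-2 (0.049). With an estimated correlation 6 list calls were lost and 6 gained with a library left out, and none with DESeq2 size factors. Depth limits genes near 12 units over a group, for which levels or counting intervals are given.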

Other observations

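The genes named in this part and the sharing of calls between lights were chosen after their values were seen.

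Several transcripts had levels that went with the npr1-1 label. AT3G55910 read 1.41 CPM in blue wild type, 1.29 in pif4-2 and 0 in npr1-1 and the double mutant, and in red 1.19, 0.885, 0 and 0.0319. The nearby locus AT3G55900 read 0.776, 0.503, 0 and 0 in blue in the same order and 0.635, 0.421, 0 and 0.0281 in red. AT3G55920, a cyclophilin-type isomerase, read 11.8, 10.9, 0.88 and 0.559 in blue and 18.1, 17, 0.727 and 0.911 in red. AT3G05945 read 15.0, 15.1, 0.443 and 0.19 in blue and 10.6, 12.4, 0.315 and 0.336 in red, while AT3G05955 read 0.132, 0.156, 1.29 and 1.38 in blue and 0.251, 0.168, 2.1 and 1.78 in red. AT4G22505 read 2.26, 3.1, 0.268 and 0.274 in blue and 0.257, 0.214, 0 and 0.0319 in red. AT4G04223 was higher with npr1-1, at 24.6 and 27.7 CPM in blue npr1-1 and the double mutant against 3.93 in wild type and 5.79 in pif4-2, and at 21.3 and 20.7 in red against 3.47 and 4.97. QQS, a regulator of starch content, read 0.511 in blue wild type, 2.1 in pif4-2, 20.7 in npr1-1 and 13.3 in the double mutant, and in red 0.288, 1.72, 25.6 and 10.2. It was also called higher in pif4-2 than in wild type (log2 2.04 in blue and 2.54 in red), and lower in the double mutant than in npr1-1 (-0.64 and -1.33).

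AT3G29633 and AT1G64795 were lower in each mutant than in wild type in both lights. AT3G29633 read 10.6 CPM in blue wild type and 0.0732, 0.0303 and 0.09 in npr1-1, pif4-2 and the double mutant, and in red 9 against 0.0789, 0.0157 and 0.0563. AT1G64795 read 19.2 against 0.52, 0.0747 and 0.00766 in blue and 4 against 0.0629, 0.0314 and 0.112 in red. AT3G01345 stood at 47.6 CPM in red pif4-2 and at 0.737 in blue pif4-2, although both carry the same genotype label. Among calls in both lights, npr1-1 shared 1956 genes in direction and 191 opposite (independent lists 656 and 658), pif4-2 150 and 93 (71 and 71) and the double mutant 638 and 80 (147 and 147).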
